A study of Mus musculus with 4 samples.

How the data were processed

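RNA was measured in 4 libraries of mouse embryonic fibroblasts, primary connective tissue cells taken from embryos at day 13.5 of gestation on a mixed C57BL/6 and 129S background. The cells lacked the H3.3B gene (H3f3b). Per the labels' protocols they were infected with lentivirus carrying a short hairpin RNA against H3.3A (H3f3a) or a scrambled control hairpin, selected with puromycin at 3 µg/ml and collected 7 days later. Total RNA was depleted of ribosomal RNA and made into strand-specific libraries, so transcripts without a poly(A) tail, such as those of replication-dependent histones, were kept. The labels name 2 libraries per group, and the series' design text calls the duplicates biological. It does not say whether they came from separate embryos, so the tests measure the spread between these libraries.

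Per the submitters' processing notes, CASAVA 1.8.2, TopHat2, Bowtie, HTSeq 0.5.4p3, DESeq and the mouse build mm9 were used, with no order or settings named. The authors deposited a table with raw read counts per gene and library, per the file headers. The shControl columns are numbered, and both shH3.3A columns bear one and the same header, so they are called the first and the second column here and carry no replicate number. The authors also deposited counts divided by a size factor and by gene length in kilobases. Of these normalized values only the shControl columns were read, to compare size factors, and the 2 normalized shH3.3A columns were not used. The ratio of the shControl size factors that these columns imply was 2.61466, the same as that of DESeq2 here, over 6926 genes with at least 500 counts in both libraries. The authors' deposited log2 fold changes, p-values and adjusted p-values come from DESeq2, per the file headers. These values are kept apart from those computed here. Numbers in the table use decimal commas.

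The table holds 24152 genes, each with a name and at least 1 count, and 139 symbols stand on several rows, mostly families of small RNA. How reads that match several copies were counted, and which strand setting was used, is not given in the sources used here. Counts of near-identical genes, among them the replication-dependent histones and the H3.3 genes with their pseudogenes, are therefore uncertain. The annotation at hand is of another build than mm9, so gene identifiers and symbols were taken from the table and no coordinates are given.

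Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr (15196) were scaled by TMM and tested by the two-sided quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was taken from the coefficient and the F statistic of that test. Values per library are CPM with TMM scaling, given as mean ± SD. The common biological coefficient of variation was 0.314. An exact rank test of 2 libraries against 2 cannot give a two-sided p under 0.333. Groups are called apart where both libraries of one lie above both of the other, which chance gives for 33.3% of genes. The 29 gene lists were fixed before the data were examined, as were the tests, the thresholds and the rule for naming genes. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry.

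The rule named H3f3a and H3f3b, then the 12 largest changes each way among genes past the threshold with a mean of at least 100 normalized counts and groups apart, then up to 4 members (mean of at least 50) of each list past the threshold and 2 of each other list. The second part named no gene, because none passed. The 12 largest differences each way among DESeq2 calls (adjusted p under 0.05, the same mean and groups apart) and the 4 genes at an edgeR adjusted p under 0.1 were therefore chosen after their values were seen.

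Alternatives fixed beforehand were DESeq2 1.42.0, median-of-ratios (RLE) and total-count scaling, no filter or a higher one, prior counts of 1, 5 and 10, thresholds of 0.01 and 0.1, a fold of 1.5, and each library left out in turn with the tested genes kept. The likelihood ratio test, voom, robust moderation, DESeq2 without each library or with other thresholds, and the filter rerun on 3 libraries were added after seeing the data. With 1 library left in a group, that library is assumed to vary like the others. Lists of 50 hepatocyte markers, of fetal liver and blood markers, and of transcripts of imprinted domains were also drawn up after the data were examined. An interval or floor from counts covers counting error only.

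The scripts were tested on simulated counts for this comparison, with the means, depths and dispersions of the 15196 genes. Of 50 genes each changed by 1, 2, 3 and 4 on the log2 scale, edgeR recovered 8%, 60%, 80% and 84%, and DESeq2 30%, 80%, 84% and 96%. edgeR made 122 calls, of which 6 were unchanged genes, and DESeq2 made 202, of which 55 were. A list of 40 genes shifted by 0.6 had a camera p of 6.46e-12 and an unshifted list of 40 one of 0.828. Genes were simulated independently of each other, so this cannot test camera at the preset correlation on correlated lists. In the real data the estimated correlation ran from -0.114 to 0.764 over the lists, and was 0.701 for the replication-dependent histones.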

Results

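Gene expression was measured by RNA sequencing in 4 libraries of H3f3b knock-out mouse embryonic fibroblasts, 2 with a control hairpin (shControl) and 2 with a hairpin against H3f3a (shH3.3A). H3f3a and H3f3b both encode histone H3.3, the H3 variant that is placed into chromatin outside DNA replication, so the comparison asks what happens to the transcriptome when the remaining H3.3 gene is knocked down. Total gene counts were 49816047 and 19405325 in shControl replicates 1 and 2, and 45537181 and 44307408 in the first and second shH3.3A columns.

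The targeted transcript was far lower in both shH3.3A libraries. H3f3a (ENSMUSG00000060743) stood at 133 ± 68.8 CPM in shControl and 8.52 ± 1.63 CPM in shH3.3A (mean ± SD, n = 2 each), a 15.6-fold difference (log2 fold change -3.97, SE 0.43). The libraries read 84.6, 182, 7.36 and 9.67 CPM, so the groups were apart and each label fits its H3f3a level. The edgeR adjusted p was 0.149, above the threshold, and the DESeq2 adjusted p was 2.23e-19, while the shControl libraries differed from each other by more than 2-fold. Without shControl replicate 1 the edgeR adjusted p was 0.00109, and without shControl replicate 2 it was 0.00696, while without the first or the second shH3.3A column it was 0.992 or 0.349. H3f3b (ENSMUSG00000016559) stood at 17.6 ± 1.35 CPM in shControl and 18.1 ± 2.84 CPM in shH3.3A, a difference within the spread of the libraries (log2 fold change 0.04, SE 0.23, edgeR adjusted p = 0.951). Both groups carry the knock-out, and the labels do not say which part of H3f3b was deleted, so its remaining counts check nothing.

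**Figure D1:**
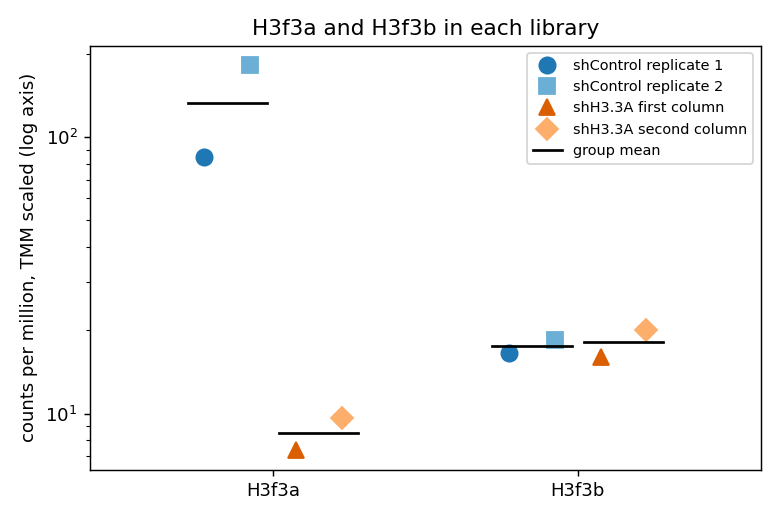
CPM (log axis) of H3f3a and H3f3b in each of the 4 libraries, with the group means as bars. H3f3a stood at 84.6 and 182 CPM in shControl and at 7.36 and 9.67 CPM in shH3.3A, and H3f3b differed by less than the spread of the libraries.

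Across the transcriptome no gene passed the edgeR quasi-likelihood test (0 of 15196 at an adjusted p under 0.05). At an unadjusted p under 0.05 there were 2291 genes, 1132 higher and 1159 lower in shH3.3A, and DESeq2 called 912 at an adjusted p under 0.05, 454 higher and 458 lower. In the simulated counts 55 of 202 DESeq2 calls were unchanged genes, against 6 of 122 for edgeR. In that simulation the share was more than the threshold of 0.05 allows, so a single DESeq2 call is weak support. The simulation changed fewer genes than DESeq2 called here and used edgeR's dispersions, so its share is not that of the 912 calls. With shControl replicate 1 grouped with the first or the second shH3.3A column, DESeq2 called 1 or 119 genes. In those groupings any difference between shH3.3A and shControl adds to the spread within groups. A difference of at least 2-fold was estimated for 2106 genes, 1285 higher and 821 lower. The groups were apart for 7600 genes, which is 50.01% of those tested against 33.3% by chance. Leaving out either shControl library raised the edgeR count, and leaving out any library moved the DESeq2 count, which was lowest without the first shH3.3A column. With a single shControl library left, the spread within groups came from the shH3.3A libraries alone. These were the most alike (SD of the log2 difference 0.613, against 1.08 between the shControl libraries). The higher edgeR counts therefore do not show a larger difference. Without shControl replicate 1 edgeR called 1045 genes and DESeq2 1567, without shControl replicate 2 they called 149 and 728, and without the first or the second shH3.3A column edgeR called 0 and DESeq2 92 or 427.

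The 4 genes nearest to the threshold were Tnfsf15 and Macc1, higher in shH3.3A, and Abi3bp and Igfbp2, lower (edgeR adjusted p = 0.0788 each). Tnfsf15, a cytokine of the tumor necrosis factor family, stood at 1.29 ± 0.02 CPM in shControl and 35.5 ± 11.7 CPM in shH3.3A (log2 fold change 4.77, SE 0.35). Macc1 stood at 2.70 ± 0.04 and 33.9 ± 5.78 CPM (log2 fold change 3.65, SE 0.26). Abi3bp, an extracellular matrix protein, stood at 400.1 ± 77.7 and 33.01 ± 7.03 CPM (log2 fold change -3.60, SE 0.26). Igfbp2, which binds insulin-like growth factors, stood at 79.1 ± 11.1 and 5.61 ± 1.71 CPM (log2 fold change -3.82, SE 0.29).

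Among genes called by DESeq2 with at least 100 normalized counts, the 12 largest higher values in shH3.3A included Acta1, Actg2 and Ankrd1. Acta1, skeletal muscle actin, read 3.88 ± 2.88 CPM in shControl and 86.2 ± 43.4 CPM in shH3.3A, and Actg2, smooth muscle actin of the gut, 4.80 ± 2.31 and 105 ± 35.2 CPM. Ankrd1, a stretch-responsive muscle gene and YAP target, read 0.91 ± 1.06 and 14.2 ± 0.42 CPM. Serpinb9b (log2 fold change 4.72), the calcium pump gene Atp2a3 (4.204), Tmem40 (3.98), the integrin gene Itga8 (3.97), Car6 (3.93), Cst6 (3.77) and Galnt3 (3.54) completed the 12 with Tnfsf15 and Macc1. Among the largest lower values after H3f3a, Sfrp2, a secreted Wnt modulator, read 1022 ± 258 CPM in shControl and 115 ± 22.6 CPM in shH3.3A. Aspn and Omd, small leucine-rich proteoglycans, read 234 ± 148 and 42.3 ± 28.9 CPM in shControl against 17.5 ± 3.01 and 3.88 ± 0.27 CPM in shH3.3A. Tppp (-3.37), the complement gene C4b (-3.36), Fbln7 (-3.27), Inmt (-3.16) and Gdf6 (-3.07) were also lower on the log2 scale. Hp, haptoglobin, was lower by the fit (-3.58), but its values of 10.6 CPM in shControl replicate 1, 0.889 in replicate 2 and 0.112 and 0.855 in the shH3.3A columns place the difference in shControl replicate 1. The fold changes of 14 of these 24 genes moved by more than 1.5 times without at least 1 library. On the log2 scale, without shControl replicate 1 Ankrd1 stood at 6.46, Car6 at 5.14, Galnt3 at 4.37, Acta1 at 3.86, C4b at -2.44 and Hp at -0.881. Leaving out shControl replicate 2 gave 5.55 for Acta1, 3.09 for Ankrd1, -3.31 for H3f3a, -2.88 for Aspn, -2.72 for Tppp, -2.50 for Omd, -2.43 for Gdf6 and -4.45 for Hp. With the first shH3.3A column left out Serpinb9b stood at 4.11, Acta1 at 3.86, Itga8 at 2.98, Cst6 at 2.38, C4b at -2.52 and Hp at -2.76, and with the second left out Itga8 stood at 4.57, Cst6 at 4.46, C4b at -5.69 and Hp at -5.65. The edgeR adjusted p of these genes other than the 4 named first lay above 0.1, and of the 24 DESeq2 calls 21, 21, 17 and 23 were still called without shControl replicate 1, shControl replicate 2, the first and the second shH3.3A column.

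**Figure D2:**
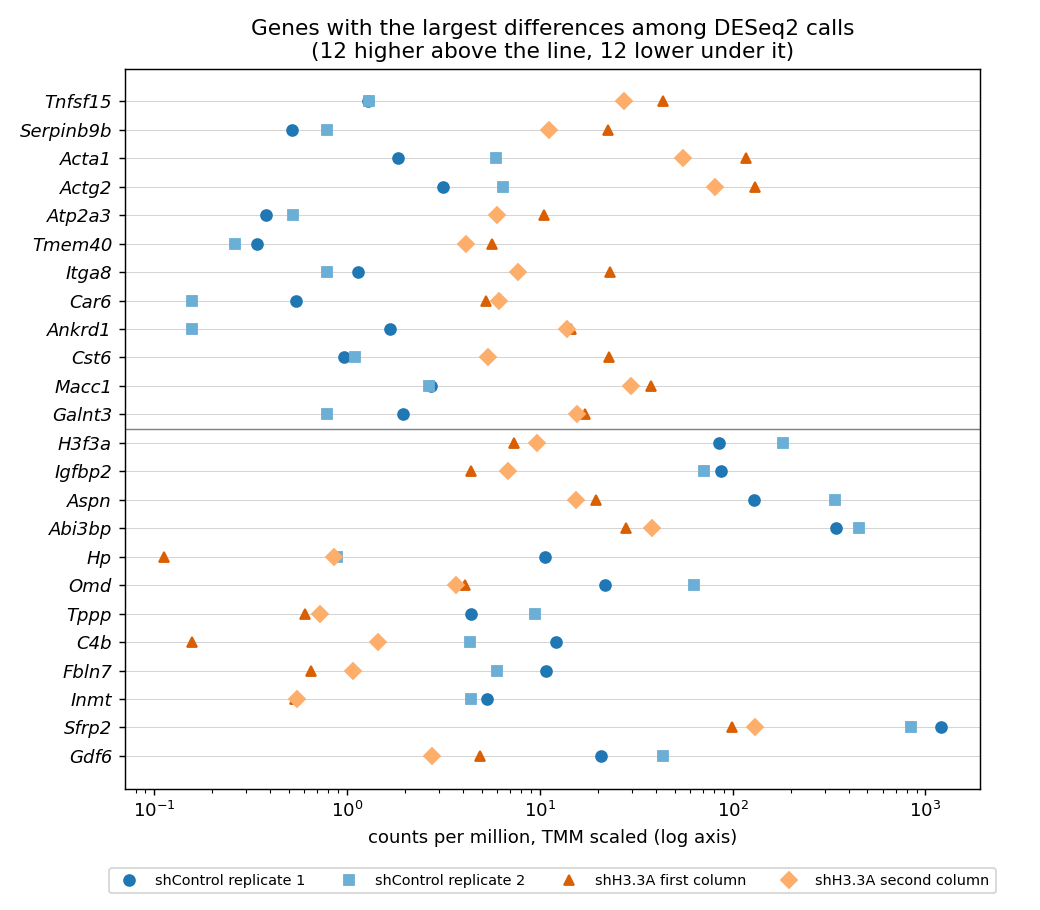
CPM (log axis) in each library for the 12 genes with the largest higher and the 12 with the largest lower values in shH3.3A among DESeq2 calls with groups apart, chosen after their values were seen. Hp differs mainly through shControl replicate 1, at 10.6 CPM.

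Genes of chromosome replication and division were lower in shH3.3A. All 52 measured replication-dependent histone genes, which supply histones in S phase, had a negative log2 fold change, with a median of -1.02, and 46 had groups apart (camera adjusted p = 2.23e-27, and adjusted p = 0.400 with an estimated correlation). Of these 34 passed edgeR when adjusted over the list alone, 24 were DESeq2 calls and 0 passed over all genes tested. Hist1h2af (log2 fold change -1.75), Hist1h1d, Hist1h3c (both -1.54) and Hist1h3h (-1.51) were the lowest at a mean of at least 50 counts. Histones took 0.59% and 0.569% of counts in the shControl libraries and 0.205% and 0.373% in the shH3.3A libraries. Of 48 DNA replication genes 46 were lower, with a median of -0.55 (camera adjusted p = 9.92e-15, and 0.400 as adjusted p with an estimated correlation), and 13 passed adjusted over the list alone. Fen1, which processes Okazaki fragments, stood at 90.1 ± 1.63 CPM in shControl and 38.3 ± 5.33 CPM in shH3.3A. It was a DESeq2 call, as were Lig1 (-1.05), Prim1 (-0.998) and Cdt1 (-0.90). Of 65 mitosis and kinetochore genes 62 were lower, with a median of -0.51 (camera adjusted p = 6.50e-14, and 0.497 as adjusted p with an estimated correlation). Against shControl replicate 1 the mitosis median was -0.34 and -0.28 in the first and second shH3.3A columns, and against shControl replicate 2 it was -0.71 and -0.62. Cenpf (-1.36), Mki67 (-1.24) and Kif14 (-1.09) were DESeq2 calls and Nusap1 (-1.10) was not, and 0 members passed adjusted over the list alone.

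Other chromatin lists were lower too. Of 14 measured members of the list of H3.3 genes and chaperones 11 were lower, with a median of -0.45 (camera adjusted p = 1.72e-05, and 0.400 as adjusted p with an estimated correlation). H3f3a and Ubn1 passed adjusted over the list alone. H3f3a is the hairpin's own target, so part of this fall was set by the treatment, and the list was not tested without it. The list also holds Hjurp and Cenpa, which belong to the centromeric variant CENP-A rather than to H3.3. Ubn1, a subunit of the HIRA complex that deposits H3.3, stood at 134 ± 6.61 CPM in shControl and 64.8 ± 5.58 CPM in shH3.3A, while Dek (-0.70) and Hjurp (-0.65) were not DESeq2 calls. Of 12 genes in the list of other histone variants 9 were lower, with a median of -0.70 (camera adjusted p = 0.00214, and 0.400 as adjusted p with an estimated correlation). H1f0 (-1.71) and H2afy2 (-1.58) led, with H1fx at -1.43 and Hist2h3b at -0.90. Hist2h3b and Hist2h3c1 in this list encode the replication-dependent H3.2, so it is not fully separate from the replication-dependent histones. Of 27 chromatin regulators 22 were lower, with a median of -0.38 (camera adjusted p = 0.000127, and 0.506 as adjusted p with an estimated correlation), with Cbx1 at -0.93, Hells at -0.68, Setd2 at -0.67 and Jarid2 at -0.66. No member of the last 2 lists passed adjusted over the list alone.

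Interferon, secreted factor and contractile genes were higher in shH3.3A. Of 47 interferon-stimulated genes 39 were higher, with a median of 0.70 (camera adjusted p = 7.53e-09, and 0.400 as adjusted p with an estimated correlation), and 14 passed adjusted over the list alone. At a mean of at least 50 counts Usp18 (2.87), Oasl1 (2.37), Oasl2 (2.35) and Gbp3 (2.16) were the highest and were DESeq2 calls at low levels, with 0.857 ± 0.176 and 6.33 ± 3.14 CPM for Usp18. Of 28 inflammatory and senescence-associated secreted factors 23 were higher, with a median of 0.74 (camera adjusted p = 2.14e-05, and 0.400 as adjusted p with an estimated correlation). Igfbp7, the 1 member past the threshold adjusted over the list alone, read 16.9 ± 8.23 and 103 ± 21.1 CPM. Ptgs2, the inducible cyclooxygenase, stood at 1.76, Ereg at 1.82, and Cxcl5 at 2.13 with overlapping groups. Of 25 contractile and serum response factor genes 20 were higher, with a median of 0.41 (camera adjusted p = 1.33e-05, and 0.400 as adjusted p with an estimated correlation), and 5 passed adjusted over the list alone. Beside Actg2 these included smooth muscle myosin Myh11 (3.27) and Synpo2 (2.54), and Cnn1 stood at 1.35. Of 10 skeletal muscle markers 8 were higher, with a median of 1.68 (camera adjusted p = 0.000112, and 0.400 as adjusted p with an estimated correlation), and Ttn (4.91), Actc1 (4.73), Acta1 and Chrna1 passed adjusted over the list alone. Ttn and Actc1 had few counts in shControl replicates 1 and 2 (4 and 2 for Ttn, 9 and 0 for Actc1). In the first and second shH3.3A columns they had 210 and 39, and 225 and 44 counts. Tnnt3 (0.77) did not pass, and its groups overlapped.

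Metabolic, stress and lineage lists were also higher by camera. Of 27 glycolysis and hypoxia genes 23 were higher, with a median of 0.45 (camera adjusted p = 0.000349, 0.497 as adjusted p with an estimated correlation, and 0.151 as adjusted p without shControl replicate 2). Ero1l (2.10) and Ndrg1 (1.05) were DESeq2 calls, as was Pfkp (18.5 ± 5.26 and 64.5 ± 10.8 CPM), Hk2 (0.99) was not, and 2 members were higher and 1 lower past the threshold adjusted over the list alone. Of 22 cholesterol synthesis genes 20 were higher, with a median of 0.40 (camera adjusted p = 0.00230, and 0.719 as adjusted p with an estimated correlation). That call was lost without shControl replicate 2 (adjusted p = 0.488) and without the first shH3.3A column (adjusted p = 0.163). Insig1 stood at 1.42, Sc4mol at 1.01, Hsd17b7 at 0.95 and Fdps at 0.86. Of 30 integrated and endoplasmic reticulum stress genes 23 were higher, with a median of 0.30 (camera adjusted p = 0.00309, and 0.497 as adjusted p with an estimated correlation), and the amino acid genes Slc7a11 (1.54), Asns (0.89), Slc7a5 (0.84) and Phgdh (0.82) were DESeq2 calls. Of 28 p53 target genes 20 were higher, with a median of 0.24 (camera adjusted p = 0.0184, and 0.617 as adjusted p with an estimated correlation). Pmaip1, which encodes the cell death protein Noxa, read 1.39 ± 0.04 and 15.8 ± 5.91 CPM, and Perp (2.42) and Plk2 (1.11) also passed adjusted over the list alone, while Eda2r (1.81) had overlapping groups. The p53 call was lost without shControl replicate 1 (adjusted p = 0.720), without the first shH3.3A column (adjusted p = 0.109) and without members shared with other lists (adjusted p = 0.0515).

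Of 26 immediate early genes 19 were higher, with a median of 0.31 (camera adjusted p = 0.0335, and 0.537 as adjusted p with an estimated correlation), and the call was lost without shControl replicate 2 (adjusted p = 0.155) and without the second shH3.3A column (adjusted p = 0.427). Atf3 (2.04) and Dusp6 (1.44) were DESeq2 calls and Egr2 (1.77) and Dusp5 (0.94) were not. Of 9 neural and glial markers 8 were higher, with a median of 1.17 (camera adjusted p = 0.00436, and 0.400 as adjusted p with an estimated correlation), among them Tubb3 (1.57), Sox2 (1.17) and Nes (0.91), and the call was lost among members at a mean of at least 50 counts (adjusted p = 0.0710). Of 8 epithelial and keratinocyte markers 5 were higher, with a median of 0.45 (camera adjusted p = 0.00991, and 0.400 as adjusted p with an estimated correlation), led by Perp, which the p53 list also holds, with Krt7 at 1.61 and Cdh1 at 0.59. This call was lost without shControl replicate 1 (adjusted p = 0.0583), without the second shH3.3A column (adjusted p = 0.0600), without members shared with other lists (adjusted p = 0.163) and with no filter on counts (adjusted p = 0.162). Of 8 germline genes 6 were higher, with a median of 0.45 (camera adjusted p = 0.0332, and 0.400 as adjusted p with an estimated correlation), and none reached a mean of 50 counts. Their call was lost without shControl replicate 1 (adjusted p = 0.177) and without shControl replicate 2 (adjusted p = 0.0617). Adjusted over the list alone, 0 members of the cholesterol, stress, immediate early and neural lists passed, 1 of the epithelial list (Perp) and 2 of the germline list (Piwil2 and Taf7l).

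By camera 18 of the 29 lists passed, 6 lower and 12 higher, and 0 passed with an estimated correlation. By fry 0 lists moved one way on balance (smallest adjusted p = 0.126) and 4 changed in either direction (smallest adjusted p = 0.0407). The other 11 lists did not pass camera, and 0 members passed adjusted over the list alone where no count is given. Oxidative phosphorylation genes had a median of 0.12 over 44 members (adjusted p = 0.135), with Cycs at 0.57 and Uqcrq at 0.56. YAP and TEAD targets had a median of 0.13 over 18 members (adjusted p = 0.213), with Ankrd1 and Ctgf (2.17) among 5 members higher and 2 lower adjusted over the list alone. Adipocyte markers stood at 0.40 over 10 (adjusted p = 0.377), with Fabp4 and Plin4 both at 1.21, and Hox genes at 0.28 over 15 (adjusted p = 0.822), with Hoxa1 at 0.97 and Hoxa3 at -0.73. Cytoplasmic ribosomal protein genes stood at 0.03 over 61 (adjusted p = 0.983), with Rpl28 at -0.56 and Rpl5 at -0.42. Mitochondrial transcripts stood at -0.10 over 13 (adjusted p = 0.793), with mt-Cytb at -0.49 and mt-Rnr2 at 0.40, and macrophage markers at -0.25 over 6 (adjusted p = 0.860), with Cd14 at -0.52.

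Some of the 11 passed in other settings. Without shControl replicate 1 the imprinted (adjusted p = 8.81e-06), adipocyte (adjusted p = 0.00291) and YAP and TEAD lists (adjusted p = 0.0282) passed as higher and mitochondrial transcripts (adjusted p = 0.0403) as lower. Chondrocyte and osteoblast markers passed as higher without the first shH3.3A column (adjusted p = 0.00645), and macrophage markers as lower with no filter on counts (adjusted p = 0.0180). Oxidative phosphorylation genes passed as higher without the second shH3.3A column (adjusted p = 0.0496) and at means of at least 50 and 100 counts (adjusted p = 0.0482 and 0.0378).

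Median, mean and test differed in sign for the remaining lists. Extracellular matrix genes had a median of -0.01, a mean of -0.12 and a camera direction of higher (59 members, adjusted p = 0.983), with 6 members higher and 6 lower adjusted over the list alone. Aspn was among those lower, and elastin (Eln, -4.21) had overlapping groups. Chondrocyte and osteoblast markers had a median of -0.19, a mean of 0.11 and a direction of higher (10 members, adjusted p = 0.793), with osteopontin (Spp1), the 1 member past the threshold adjusted over the list alone, at 59.5 ± 0.634 CPM in shControl and 483 ± 234 CPM in shH3.3A, and Satb2 at -0.83. Endothelial markers had a median of -0.01, a mean of 0.07 and a direction of higher (11 members, adjusted p = 0.844), with Ramp2 at -1.38 and Kdr at 1.06. Imprinted genes had a median of 0.18, a mean of -0.02 and a direction of higher (20 members, adjusted p = 0.879). Among them Grb10 read 42.2 and 649.5 CPM in shControl and 20.8 and 139 CPM in shH3.3A, and H19 9.43, 1.10, 19.7 and 10.8 CPM.

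**Figure D3:**
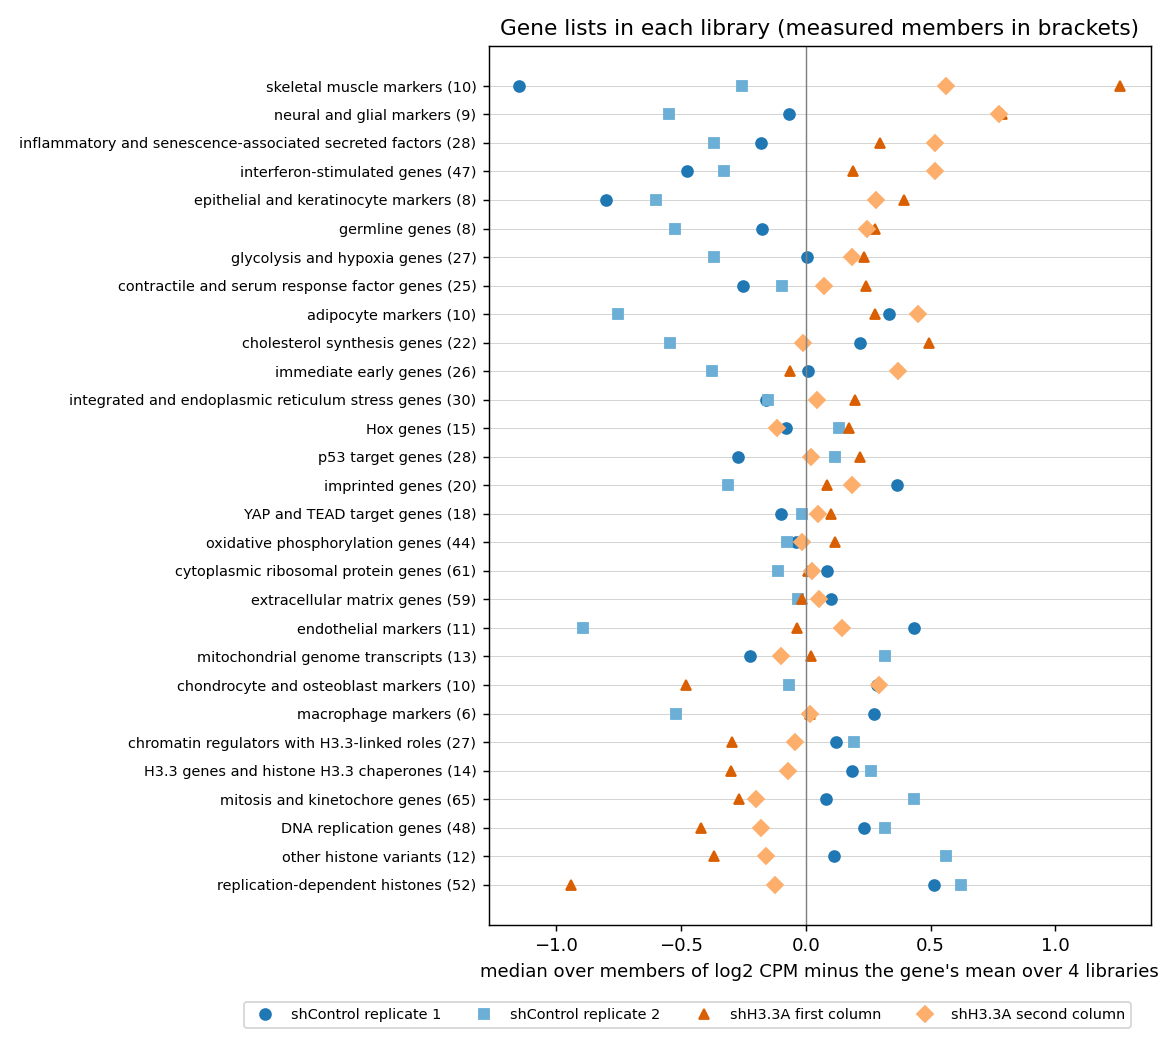
Median over the members of each of the 29 lists of log2 CPM minus the gene's mean over the 4 libraries, 1 point per library, with lists ordered by their median log2 fold change. The replication-dependent histones stood at 0.51 and 0.62 in shControl and at -0.94 and -0.12 in shH3.3A.

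The libraries of a group were not alike. The SD of the log2 difference over genes was 1.08 between the shControl libraries, 0.613 between the shH3.3A libraries, and 0.751 to 1.13 between libraries of different groups. The first principal component (54.3% of variance) set shControl replicate 2 apart, and the second (37.8%) had shControl replicate 1 and the first shH3.3A column at its ends. Transcripts of hepatocytes, the main cell of the liver, were abundant in shControl replicate 1. Alb, serum albumin, read 728 CPM there, 12.3 CPM in shControl replicate 2, 45.2 CPM in the second shH3.3A column and 0 counts in the first, which allows up to 0.0671 CPM. Some transcripts of imprinted genes were nearly missing from shControl replicate 2, where Rian, Meg3 and Peg3 had 1 count each and Mirg 0, against 221, 69.5, 73.9 and 13.1 CPM in shControl replicate 1. In the shH3.3A columns these 4 read 155 and 243, 53.7 and 90.5, 47.1 and 55.8, and 8.82 and 17.8 CPM.

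**Figure D4:**
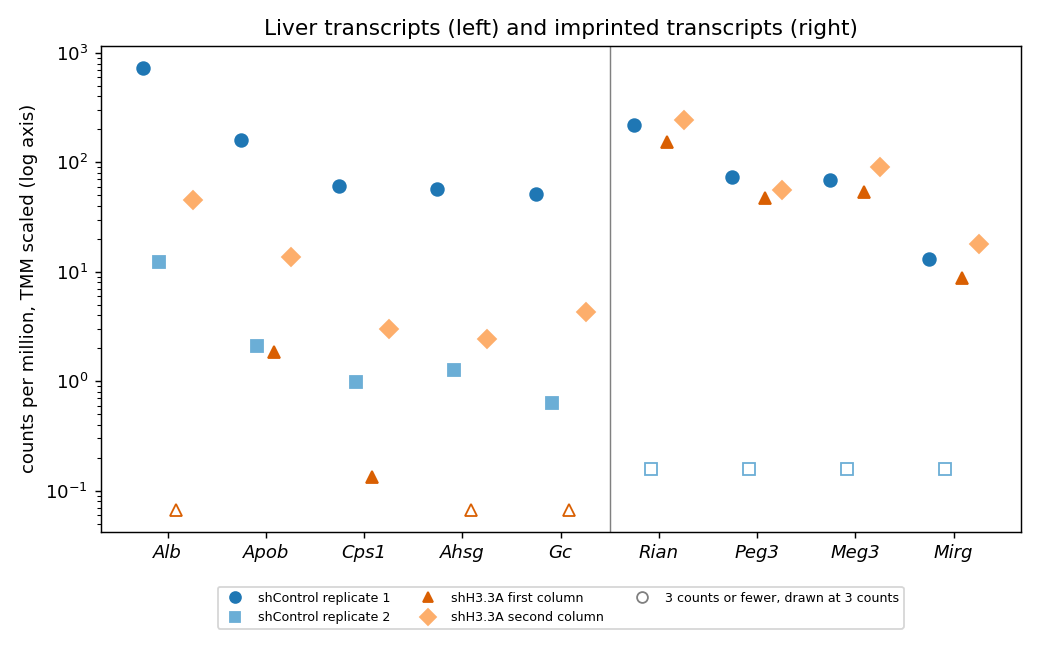
CPM (log axis) in each library of 5 liver and 4 imprinted transcripts, with values of 3 counts or fewer drawn open at 3 counts. Alb reached 728 CPM in shControl replicate 1, and Rian had 1 count in shControl replicate 2.

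In the authors' deposited table, 941 of 24152 genes had an adjusted p under 0.05, 482 higher and 459 lower. Of the genes called in the authors' deposited table, 496 were also called by DESeq2 here, 445 were called there alone, and 416 were called here alone. Per the series' design text the authors analysed pooled data from biological duplicates. The sources used here do not name the libraries behind the authors' deposited test. The ratio of the deposited shControl size factors was that of DESeq2 on all 4 libraries here. The deposited fold changes lay closest to a fit without shControl replicate 2, as given below. These overlaps may therefore compare calls from different libraries. H3f3a had a log2 fold change of -3.11 in the authors' deposited table (adjusted p = 1.14e-22). DESeq2 fits with shrunken fold changes gave -3.21 for it on all 4 libraries and -2.92 without shControl replicate 2, so this gene lay nearer the former. The -3.97 given above is not shrunken. Over 12163 genes the fold changes of the authors' deposited table had a Spearman correlation across genes of 0.866 with those of a DESeq2 fit with shrunken fold changes on all 4 libraries. The same fit without shControl replicate 2 gave 0.993 against the authors' deposited table, with a median absolute difference of 0.0212 on the log2 scale in place of 0.121, and shared 641 of the 941 calls in place of 475. Without shControl replicate 1, the first or the second shH3.3A column the correlation with the authors' deposited table was 0.598, 0.732 and 0.874. Genes are not independent replicates, so these correlations carry no test.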

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

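The likelihood ratio, voom and robust tests, the other DESeq2 settings and the filter rerun were chosen after seeing the data. The edgeR count of 0 stayed 0 under higher filters, voom, robust moderation and a threshold of 0.01, and under both other scalings, which moved the median log2 fold change by at most 0.0163 and so test little. It was 5 with no filter, 4 at 0.1, 682 by the likelihood ratio test and 912 by DESeq2. Leaving out single libraries gave 0 to 1537, where 1537 and 332 (shControl replicates 1 and 2) came with the filter rerun and 1045 and 149 with the tested genes kept. Genes past 2-fold (2106) were 8128 with no filter, 1194 and 921 at means of at least 50 and 100, 4310 at 1.5-fold, and 2021 to 3501 without single libraries. DESeq2 calls were 513 at 0.01 and 92 to 1567 without single libraries, the lowest without the first shH3.3A column. In the authors' deposited table, 602 genes passed 0.01. The H3f3a log2 fold change passed the threshold by DESeq2 (-3.965) and without either shControl library, and ranged from -4.425 to -3.312 without single libraries, with edgeR adjusted p from 0.00109 to 0.992. Camera called 14 to 19 lists without single libraries and 0 with an estimated correlation. Of the 18 lists called, 11 kept call and direction in every setting they were run in other than the estimated correlation, and 3 had too few members for all 11 settings. No result past its threshold reversed, and values short of it changed sign in 9 fits of named genes and 19 of lists. Medians of called lists moved by more than the spread between replicates in 27 fits and stayed in 117, and none changed sign. Where the filter or the fold threshold changed the count of genes past 2-fold, more or fewer genes were counted by construction, and for the rest the cause was not tested. No paired analysis was possible because the shH3.3A columns carry no replicate number. At 19405325 counts, shControl replicate 2 limits what can be said of genes with few counts.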

Other observations

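The explanations in this part and their tests were chosen after the results were seen. Camera, its estimated correlation and DESeq2 were fixed beforehand.

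Liver transcripts stood out in shControl replicate 1. Of 50 hepatocyte markers, none in a list fixed beforehand, 48 had at least 100 counts, and 46 of these (95.8%) were highest in shControl replicate 1, led by Alb (728 CPM), Apob (161 CPM) and Cps1 (61.4 CPM). The exceptions were Mup20 and Itih2, and Itih2 read at least 34.5 CPM in every library. Liver cells carried over from the embryos are argued against, since Afp, the main serum protein transcript of fetal liver, had 0 counts there (0% of the 36351 Alb counts), with 204 counts over the red cell markers. A lowering by the knock-down in both shH3.3A libraries is argued against too. The markers were lower in shControl replicate 2 than in the higher shH3.3A library (median log2 ratio -1.97, quartiles -2.68 and -1.27). That library was mostly the second column, and the first was not tested as a set. More of the 48 markers were lower in the first column than in shControl replicate 2, such as Alb, than were higher, such as Hpx. Most had few counts in both libraries. A lowering in the first column alone is therefore not excluded. RNA or reads of adult liver remain a candidate source, and the counts do not show at which step they entered. The signal was not confined to that library, since 45 of the 48 markers (93.75%) were higher in the second shH3.3A column than in the first. Of the 48 markers 2, Hp and Itih1, were DESeq2 calls here, and 25 passed an adjusted p of 0.05 in the authors' deposited table. The libraries behind that test are not named, and its fold changes lay closest to a fit without shControl replicate 2.

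Some imprinted transcripts were nearly missing from shControl replicate 2. Of 33 imprinted genes in the table, 5 (Peg3, H19, Meg3, Rian and Mirg) were at least 8-fold lower there than in each other library, and 0 were in any other library. The rule also asked for a minimum of expected counts. Imprinted genes with few counts in every library, such as Igf2 and Nnat, could therefore not qualify and were not shown to be kept. Meg3, Rian and Mirg share the Dlk1-Dio3 domain, so the 5 are not independent. Others were not low there, such as Gnas (894 CPM) and Grb10 (649.5 CPM). Dio3, of that same domain, read 17.5 CPM there, against 3.42 CPM in shControl replicate 1 and 1.12 and 2.61 CPM in the shH3.3A columns. Depth is argued against by the counts expected at this library's depth, with 1 count of Rian against 4235, 1 of Meg3 against 1328 and 1 of Peg3 against 1067. Over these 5 genes together the observed counts were 0.339% of those expected. The genes were picked as low after scaling for depth, so that sum had to be small and tests little. H19 was the least depleted, with 21 counts against 207 expected. An shH3.3A library under a control label is also argued against, since H3f3a stood 18.8 times above the higher shH3.3A library. A culture of another origin and silencing within the culture cannot be told apart, because either could leave these 5 genes low and the labels name neither embryo nor passage. Whether a culture of another origin would lack them was not tested. Among all genes 82 were at least 8-fold lower in this library than in each other one, against 11, 11 and 0 for shControl replicate 1 and the first and second shH3.3A columns.

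The histone, replication and mitosis lists were lower with shH3.3A. A direction set by one control library is argued against, since the median over members was negative in all 12 pairs of list, shH3.3A and shControl library, the highest being -0.279. The signs do not show that the size was free of one control library. For the mitosis list the median gap of shControl replicate 1 to replicate 2 was -0.36. The shH3.3A columns differed from shControl replicate 1 by -0.34 and -0.28, so much of that list's median came with shControl replicate 2. A scaling factor per library shifts every gene alike and is argued against as well, since the highest of these 12 medians was -0.276 after the median of all tested genes was subtracted. An effect of the knock-down stays open as a hypothesis, as does any other difference between these cultures, because with 2 libraries per group the smallest adjusted p of these lists with an estimated correlation was 0.400. The 3 splits of the 4 libraries are too few for a share under 0.05. The real split gave 18 lists by camera and a histone median of -1.02, and the others gave 10 and 11 lists and histone medians of 0.31 and -0.23.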
